A study of Rattus norvegicus with 9 samples.

How the data were processed

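Gene expression was measured by poly-A selected RNA sequencing in primary chondrocytes, the matrix-forming cells of cartilage, from Sprague-Dawley rats, used at passage 1 or 2. There were 3 groups of 3 libraries, each sampled after 24 h: rat plasma alone (RP), rat plasma with thrombin (RPT), and rat plasma with thrombin and an inhibitor that the labels do not name (RPTi). Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 libraries of a group came from separate animals or separate cultures, so p-values measure only the spread between these samples, which may be technical.

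The deposited table held whole-number read counts per Ensembl rat gene, made by the authors on the genome build Rnor_6.0. The submitters' processing notes name HISAT2, HTSeq 0.11.2 and DESeq2 1.26.0 among the tools, and give neither roles nor order. The HISAT2 version, the annotation release, the strand setting of the counting and any filter are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical gene copies are therefore uncertain. The same table held FPKM values per library, which the authors computed from their counts: dividing each count by a whole-number gene length and by the library total gave the deposited FPKM with a largest relative difference of 2.2e-13. Such a length fitted every one of the 18924 genes within a relative tolerance of 1e-06. The tests below use the counts, and FPKM entered only 1 alternative. No row lacked a gene name. The reference gene table supplied with the data is for assembly GRCr8, another build than the files use, so it served only to match older symbols, and no coordinates are printed.

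Library totals ranged from 31877265 to 43962783 counts, and 1 count corresponded to between 0.0227 and 0.0314 CPM (counts scaled to library size). Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 13856 of 18924 genes and removed 0.026% of all counts. Libraries were scaled by TMM. One quasi-likelihood model (glmQLFit and glmQLFTest in edgeR 4.0.16, R 4.3.3) was fitted to all 9 libraries with 1 coefficient per group, so that the groups shared an estimate of spread, and the contrasts RPT minus RP, RPTi minus RPT and RPTi minus RP were tested, together with an F test over the 3 groups. Genes with a Benjamini-Hochberg adjusted p below 0.05 are said to have risen or fallen. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic, and CPM values are TMM-scaled means with the SD over 3 libraries. All adjusted p-values of single genes in the text come from this edgeR test unless another tool is named. Folds of genes near the count limit depend on edgeR's prior count of 0.125.

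A gene was called opposed when it passed the threshold in RPT against RP and, with the opposite sign, in RPTi against RPT. Because these contrasts share the RPT libraries, 20 data sets with no effect were simulated from the means over all 9 libraries and the fitted dispersions. Genes were drawn independently of each other. The overlap of independent lists was computed per direction. For the 23 gene lists, limma's camera (3.58.1) was run on voom-weighted log2 CPM with a preset correlation between genes of 0.01, adjusted over 69 tests of list and contrast. An estimated correlation and limma's fry were the alternatives. The lists covered inflammatory mediators, matrix-degrading proteases, cartilage matrix and chondrocyte identity, hypertrophic chondrocyte and osteoblast markers, fibroblast-type markers, genes responsive to ERK, STAT3, NF-kB, interferon, TGF-beta, p53 and NRF2, cell cycle, contractile, coagulation, hypoxia and glycolysis, ER stress, cholesterol synthesis, mitochondrially encoded genes, and markers of macrophages, endothelium, blood cells, and muscle and fat. Of the listed symbols, 31 matched no row and are not analysed here, among them Tnf, Csf2, Mmp8, Serpina3n, Cfb, F2 and the globin genes. A further 6 lists, described only in the closing observations, were written after the per-gene results had been seen.

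The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named 17 genes of the thrombin, ERK and STAT3 pathway and of cartilage breakdown in every comparison, the 6 largest rises and 6 largest falls (3 of each for RPTi against RP) among called genes with an assigned symbol, a mean of at least 5 CPM and no overlap between groups, up to 2 called members of each list with the smallest p (up to 4 for inflammatory mediators, proteases and cartilage matrix), the 6 opposed genes with the largest thrombin change, and the 2 most abundant members of each list of other cell types. Not every gene that the rule names is printed, and genes outside it are said to be so where they appear.

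The alternatives were DESeq2 size factors in edgeR, library totals alone, no filter on low counts, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) for genes with a mean FPKM of at least 0.5, a fit of only the groups compared, the replicate number as a block, an added limit of 1 on the size of the log2 fold change, and leaving out each library in turn. Replicates were compared by a chi-square test of their counts, and every pair differed by more than sampling noise. The test was tried on simulated counts with 200 changed genes, and 13704 of the simulated genes passed the filter. For RPT against RP it recovered 50% of genes changed 1.41-fold, 86% of genes changed 2-fold, 96% of genes changed 4-fold and 16% of genes with the smallest simulated change, and called 8 of the 13505 unchanged genes that passed it (0.1%). For RPTi against RPT the recovered shares were 48%, 84%, 94% and 18%. Among 22 lists with no simulated shift, 0 passed camera at the preset correlation, and the 1 shifted list did. Genes were simulated independently of each other, so this could not show whether the preset correlation is high enough. With other splits of the real libraries, a median of 17 of 69 list tests passed. Figures were drawn with matplotlib.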

Results

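RNA from rat chondrocytes was sequenced in 9 libraries after 24 h in rat plasma alone (RP, n = 3), in plasma with thrombin, the protease that converts fibrinogen to fibrin and signals through protease-activated receptors (RPT, n = 3), or in plasma with thrombin and an unnamed inhibitor (RPTi, n = 3). The series asks by which signals thrombin acts on chondrocytes and names the MEK, ERK and Stat3 pathway. Library totals were 33520888 to 43962783 counts for RP, 31877265 to 37009972 for RPT and 31914905 to 37125039 for RPTi. Between 16009 and 16452 genes had a count. Mitochondrially encoded genes took 2.67% to 3.29% of the counts, with ranges that overlapped between the groups. The 20 most abundant genes took 17.3% to 17.5% of the counts in RP, 15.7% to 16.0% in RPT and 18.8% to 19.1% in RPTi, so this share differed between the groups with no overlap, in the same order as the collagen and aggrecan counts given below.

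The first principal component of log2 CPM, with 47.2% of the variance, placed the RPT libraries at 40.0 to 42.9, the RP libraries at -4.47 to -3.11 and the RPTi libraries at -37.7 to -35.8. On the second component, with 17.8%, the RP libraries lay below 0 and both thrombin groups above it. Correlations of log2 CPM were 0.988 to 0.991 within groups, and the lowest between groups, 0.965, was found between RPT and RPTi. Across the 3 groups, 6471 of 13856 tested genes differed.

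**Figure D1:**
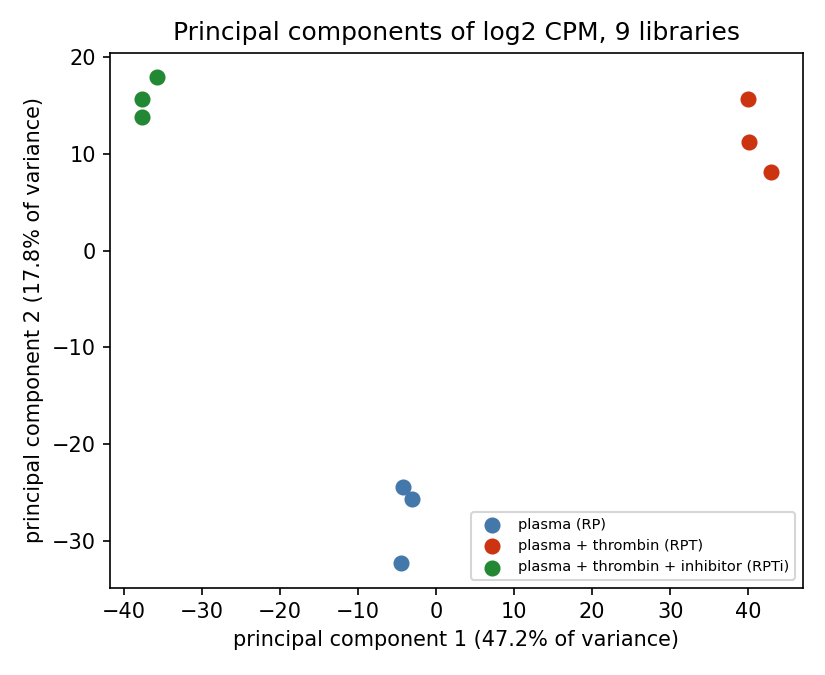
Principal components 1 (47.2% of variance) and 2 (17.8%) of log2 CPM, with 1 point per library and 1 colour per group. The 3 libraries of each group lie together, and on component 1 the RP libraries (-4.47 to -3.11) lie between the RPT libraries (40.0 to 42.9) and the RPTi libraries (-37.7 to -35.8).

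Thrombin raised genes of inflammation and lowered genes of the cartilage matrix, although neither list passed when the correlation between genes was estimated (adjusted p = 0.0528 and adjusted p = 0.0704 with an estimated correlation). C3 (ENSRNOG00000046834), the central complement component, went from 0.370 ± 0.0764 CPM in RP to 29.0 ± 2.94 CPM in RPT (SD, n = 3). The collagenase activator Mmp3 (stromelysin 1) rose from 9.43 ± 0.819 to 183 ± 16.2 CPM, a 19.3-fold change. Col2a1, the main collagen of cartilage, fell from 26060 ± 1020 to 16200 ± 1150 CPM, and the aggrecan gene Acan fell from 6927 ± 442 to 5114 ± 370 CPM. In all, 1886 genes rose and 2113 fell, and of those changed by at least 1 on the log2 scale 217 rose and 494 fell. The balance of all called genes turned without TMM factors (2119 rose and 1975 fell, 51.8% rising against 47.2%) and on log2(FPKM + 1) (54.2% rising).

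The 6 largest rises under the naming rule were C3 (log2 fold change 6.30, SE 0.19), Chi3l1, a secreted glycoprotein of cartilage and inflamed tissue (4.81, SE 0.14), Mmp3 (4.27, SE 0.11), the secreted phospholipase Pla2g2a (4.06, SE 0.14), the acute-phase protein Lcn2 (3.98, SE 0.11) and the joint lubricant Prg4 (3.80, SE 0.08). The 6 largest falls were the fibulin gene Efemp1 (-2.38, SE 0.17), the myosin light chain kinase gene Mylk (-2.23, SE 0.09), Tril (-2.21, SE 0.15), Rflna (-2.02, SE 0.17), the dynein subunit gene Dync1i1 (-2.02, SE 0.14) and the receptor tyrosine kinase gene Kit (-2.01, SE 0.11). Adjusted p-values of these 12 genes were 2.91e-06 or lower.

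Of 18 tested inflammatory mediators, 12 rose, 1 fell and 5 did not pass (camera adjusted p = 2.8e-08, and adjusted p = 0.0528 with an estimated correlation). The neutrophil chemokines Cxcl1 and Cxcl3 rose 6.58-fold and 14.2-fold, the monocyte chemokine Ccl2 rose 6.25-fold, and Ptges, which makes prostaglandin E, rose 3.92-fold. Il6 rose from only 0.123 ± 0.0735 to 0.764 ± 0.0559 CPM (log2 fold change 2.55, SE 0.48, adjusted p = 0.00165). Il1b, below the filter and not tested, had 0 counts in each RP library and 6, 9 and 3 in the RPT libraries. Of 17 NF-kB-responsive genes, 12 rose and 2 fell (adjusted p = 2.11e-05, and 0.0483 as adjusted p with an estimated correlation), among them the mitochondrial superoxide dismutase Sod2 (1.49, SE 0.07). STAT3-responsive genes rose in 9 of 20 cases and none fell (adjusted p = 0.00176, and adjusted p = 0.0894 with an estimated correlation). Interferon-stimulated genes moved the other way, with 0 rising and 6 of 18 falling, Stat2 among them (adjusted p = 0.00457, and adjusted p = 0.0664 with an estimated correlation).

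Cartilage matrix and chondrocyte identity genes fell in 21 of 24 cases, while 2 rose and 1 did not pass (camera adjusted p = 5.14e-12, and adjusted p = 0.0704 with an estimated correlation). Those with the smallest p were the intermediate layer protein gene Cilp (-1.97, SE 0.10), the matrilin gene Matn1 (-1.36, SE 0.07) and Ucma, which encodes a secreted cartilage protein (-1.14, SE 0.07). Sox9, the transcription factor of chondrocyte identity, fell 1.60-fold, while Prg4 was one of the 2 that rose. Hypertrophic chondrocyte and osteoblast markers fell in 7 of 13 cases, with the phosphatase gene Alpl at -1.31, and 1 rose, the osteopontin gene Spp1 (1.23, SE 0.09; list adjusted p = 0.0285, adjusted p = 0.11 with an estimated correlation, and 0.0523 without RPT replicate 3). Fibroblast-type markers did not pass as a list (adjusted p = 0.311): 4 rose, including Fn1, and 7 fell, including Col1a1 (-0.87, SE 0.07) and Col3a1 (-0.54, SE 0.05).

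Matrix-degrading proteases went both ways, with 5 of 20 rising, 8 falling and 7 not passing. Mmp3 and Mmp10 rose 19.3-fold and 16.2-fold, and the collagenase Mmp13 rose 1.41-fold. The aggrecanase Adamts5 fell 1.83-fold, Adamts9 fell 3.08-fold and Adamts15 fell too (log2 fold change -1.38, SE 0.10). The list did not pass camera, which ranked it down (adjusted p = 0.782), while its mean log2 fold change was 0.32 and its median 0.01.

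ERK-responsive and immediate early genes rose in 20 of 27 cases and none fell (camera adjusted p = 2.8e-14, and 0.00777 as adjusted p with an estimated correlation). The growth factor gene Hbegf rose 2.78-fold and the AP-1 gene Fosl1 3.35-fold. Of 29 cell cycle genes, 18 rose and none fell (adjusted p = 2.2e-09, and adjusted p = 0.00777 with an estimated correlation), with the replication helicase subunits Mcm3 and Mcm7 both at a 1.45-fold rise. Hypoxia and glycolysis genes rose in 14 of 20 cases, including Vegfa (2.25-fold) and the glucose transporter gene Slc2a1 (1.74-fold), and 1 fell (adjusted p = 5.89e-07, and adjusted p = 0.0268 with an estimated correlation). ER stress and amino acid response genes rose in 9 and fell in 2 of 20 cases, led by Trib3 and Sesn2, which respond to amino acid shortage. Their list passed camera (adjusted p = 0.0248), but not with an estimated correlation (adjusted p = 0.163) or a replicate block (adjusted p = 0.0789). Cholesterol synthesis genes fell in 10 of 21 cases and none rose, Stard4 (-0.63, SE 0.07) and Nsdhl (-0.44, SE 0.07) with the smallest p (adjusted p = 9.02e-05, adjusted p = 0.174 with an estimated correlation). TGF-beta-responsive genes rose in 11 and fell in 3 of 20 cases (adjusted p = 0.0019, adjusted p = 0.082 with an estimated correlation), as in Pmepa1 (1.36, SE 0.07). Coagulation and fibrinolysis genes rose in 9 and fell in 3 of 18 cases (adjusted p = 0.00478, adjusted p = 0.0926 with an estimated correlation), with the thrombin inhibitor Serpine2 up 1.70-fold. NRF2 and metallothionein genes rose in 6 and fell in 1 of 15 cases, with the metallothionein genes Mt2A and Mt1 up 2.14-fold and 2.26-fold (adjusted p = 0.0337, adjusted p = 0.138 with an estimated correlation, and 0.0624 without RPT replicate 3).

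Lists that did not pass in this comparison were the p53-responsive genes (4 rose and 2 fell of 13, adjusted p = 0.072), the contractile genes (4 rose and 6 fell of 21, adjusted p = 0.83) and the mitochondrially encoded genes (4 rose and 0 fell of 13, adjusted p = 0.0859). The mitochondrially encoded list passed without RP replicate 3 (adjusted p = 0.0242) or RPT replicate 2 (0.0407), and the p53-responsive list without RPT replicate 3 (0.0469) or with a replicate block (0.0402). Of 6 macrophage markers 2 rose and 2 fell, with Cd14 at 21.4 ± 1.97 CPM in RP and 40.3 ± 0.943 CPM in RPT (SD, n = 3). Of 4 endothelial markers 2 rose, Plvap among them at 3.32 ± 0.734 CPM in RPT, none of 2 blood cell markers passed, and of 9 muscle and fat markers 1 rose and 3 fell. The other endothelial marker that rose, Flt1, did not pass without RP replicate 2 (adjusted p = 0.106), RP replicate 3 (0.0821) or RPT replicate 3 (0.145). Adjusted over the list alone, the counts were 21 rising for ERK-responsive genes, 20 rising for cell cycle genes, 14 falling for cholesterol synthesis genes, 4 falling for ER stress genes, 5 rising for p53-responsive genes, 5 rising and 7 falling for contractile genes, 2 falling for hypoxia genes and 4 falling for TGF-beta-responsive genes, and they equalled those over all genes in the other lists.

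The transcripts of the pathway named by the series changed little with thrombin. Stat3 was at 267 ± 3.19 CPM in RP and 258 ± 3.05 CPM in RPT (log2 fold change -0.06, adjusted p = 0.451), and the ERK gene Mapk3 (-0.08, adjusted p = 0.455) and the MEK gene Map2k2 (0.01, adjusted p = 0.98) did not pass either. The other MEK gene, Map2k1, was at 0.22 (SE 0.08) and lay at the threshold (adjusted p = 0.05). Of the thrombin receptor genes, F2r fell slightly (-0.26, SE 0.08, adjusted p = 0.0237), F2rl1 rose 1.95-fold, F2rl2 did not pass at 0.492 ± 0.0377 CPM in RP, and F2rl3 was below the filter.

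The calls of Mmp13 and F2r hung on single libraries. Mmp13 did not pass without RP replicate 2 (log2 fold change 0.41), RPT replicate 1 (0.42) or RPT replicate 3 (0.46), F2r did not pass without RP replicate 1 (-0.22), RPT replicate 1 (-0.26) or RPT replicate 2 (-0.21). Map2k1, not called here, passed under 8 of its alternatives, among them DESeq2 (adjusted p = 0.0247).

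**Figure D2:**
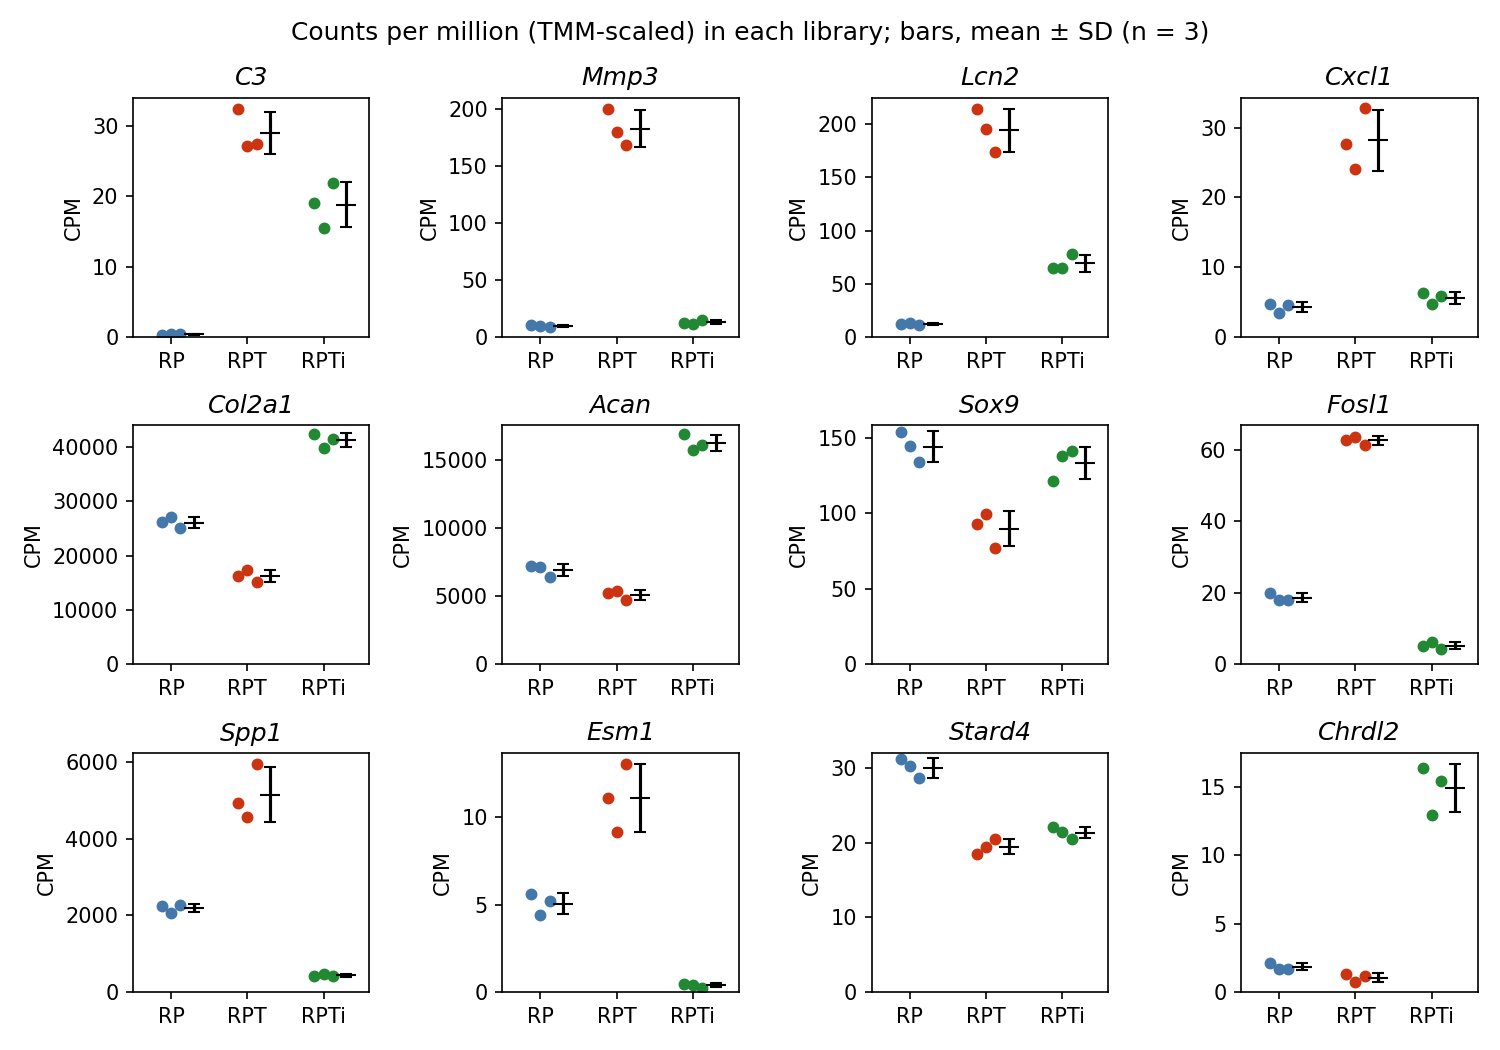
TMM-scaled CPM of 12 genes (vertical axes from 0, a separate scale for each gene), with 1 coloured point per library for RP, RPT and RPTi, and bars showing the mean ± SD (n = 3). C3 goes from 0.370 CPM in RP to 29.0 in RPT and 18.8 in RPTi, while Col2a1 goes from 26060 CPM to 16200 and 41200.

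With the inhibitor present, inflammatory, ERK-responsive and cell cycle genes were lower than with thrombin alone and cartilage matrix genes were higher. The inflammatory and cartilage lists did not pass with an estimated correlation (adjusted p = 0.0704 and adjusted p = 0.0625 with an estimated correlation). Mmp3 was 13.9-fold lower, at 13.1 ± 1.88 CPM against 183 ± 16.2 CPM (SD, n = 3). Acan was 3.18-fold higher, at 16260 ± 614 CPM, and Col2a1 was 2.54-fold higher, at 41200 ± 1320 CPM. Altogether 2825 genes rose and 2920 fell between RPT and RPTi, and of those changed by at least 1 on the log2 scale 801 rose and 495 fell.

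Under the naming rule, with its limit on CPM, the largest falls were those of Esm1, a secreted proteoglycan (-4.89, SE 0.23), the interleukin 33 receptor gene Il1rl1 (-4.07, SE 0.12), Mmp3 (-3.80, SE 0.11), the chromatin protein gene Hmga1 (-3.79, SE 0.12), Fosl1 (-3.59, SE 0.12) and Spp1 (-3.58, SE 0.10). Under the same rule the largest rises included those of the chordin-like gene Chrdl2 (3.81, SE 0.20), Wfdc1 (3.78, SE 0.13), the adhesion molecule gene Cntn2 (3.73, SE 0.13), the calcium-binding calsequestrin gene Casq2 (3.05, SE 0.14) and the sphingomyelinase gene Smpd3 (2.96, SE 0.08). Adjusted p-values of these 11 genes were 1.25e-08 or lower.

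Cartilage matrix and chondrocyte identity genes rose in 20 of 24 cases and 2 fell, Prg4 among the latter (camera adjusted p = 2.8e-14, and adjusted p = 0.0625 with an estimated correlation). Ucma rose 3.70-fold and the proteoglycan gene Fmod 2.98-fold. Of the inflammatory mediators, 12 of 18 fell and 1 rose (adjusted p = 2.21e-06, and adjusted p = 0.0704 with an estimated correlation), with Ccl2 5.82-fold lower, Cxcl1 5.02-fold lower and the cyclooxygenase gene Ptgs2 3.38-fold lower. ERK-responsive genes fell in 23 of 27 cases and none rose (adjusted p = 2.74e-16, and 0.00777 as adjusted p with an estimated correlation), the phosphatase gene Dusp5 6.23-fold. Cell cycle genes fell in 26 of 29 cases and none rose (adjusted p = 7.34e-11, and adjusted p = 0.00777 with an estimated correlation), with the ribonucleotide reductase gene Rrm2 at -0.55.

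Proteases again split, with 8 rising and 7 falling of 20 (adjusted p = 0.689). Mmp13 was 5.95-fold lower and the serine protease gene Htra1 2.23-fold lower, whereas Adamts12, Adamts15 and Adamts5 were 4.17-fold, 3.98-fold and 2.77-fold higher. Contractile genes rose in 11 and fell in 3 of 21 cases (adjusted p = 0.0012, adjusted p = 0.352 with an estimated correlation), with smooth muscle actin, Acta2, 6.89-fold higher and the leiomodin gene Lmod1 3.98-fold higher. NRF2 and metallothionein genes fell in 10 of 15 cases and none rose (adjusted p = 2.95e-05, adjusted p = 0.0361 with an estimated correlation), including Mt2A and the quinone reductase gene Nqo1. NF-kB-responsive genes fell in 10 and rose in 1 of 17 cases, the adhesion molecule gene Icam1 being the one that rose (adjusted p = 0.0114, adjusted p = 0.129 with an estimated correlation). Hypoxia and glycolysis genes fell in 12 and rose in 3 of 20 cases (adjusted p = 0.00478, adjusted p = 0.0894 with an estimated correlation), and coagulation genes fell in 10 and rose in 4 of 18 cases (adjusted p = 0.0193, adjusted p = 0.138 with an estimated correlation).

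ER stress and amino acid response genes rose in 10 and fell in 1 of 20 cases (adjusted p = 0.00336, adjusted p = 0.0966 with an estimated correlation), Atf3 by 2.88-fold. Cholesterol synthesis genes fell in 10 of 21 cases and none rose (adjusted p = 0.00233, adjusted p = 0.289 with an estimated correlation), Hsd17b7 by 1.90-fold. Lists that did not pass were the STAT3-responsive genes (2 rose and 8 fell of 20, adjusted p = 0.057), hypertrophic markers (6 rose and 3 fell of 13, 0.0962), interferon-stimulated genes (7 rose and 1 fell of 18, 0.173), TGF-beta-responsive genes (8 rose and 9 fell of 20, 0.717), fibroblast-type markers (4 rose and 6 fell of 16, 0.503), p53-responsive genes (3 rose and 6 fell of 13, 0.428), mitochondrially encoded genes (0 rose and 1 fell of 13, 0.421), and markers of macrophages (0 rose and 2 fell of 6), endothelium (0 rose and 2 fell of 4), blood cells (0 of 2 passed) and muscle and fat (4 rose and 2 fell of 9). The STAT3-responsive list passed without RP replicate 3 (adjusted p = 0.0477), RPT replicate 3 (0.0294) or RPTi replicate 3 (0.0258). Adjusted over the list alone, 14 inflammatory mediators, 10 STAT3-responsive, 11 NF-kB-responsive, 11 coagulation, 13 hypoxia, 11 NRF2 and 2 interferon-stimulated genes fell, 7 hypertrophic, 3 STAT3-responsive, 12 contractile and 12 ER stress genes rose, and the other counts were as over all genes.

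Among the pathway genes, Map2k1 was lower with the inhibitor (-0.36, SE 0.08, adjusted p = 0.00217), while Stat3 (-0.02, adjusted p = 0.825), Mapk3 (-0.03, adjusted p = 0.783) and Map2k2 (0.24, adjusted p = 0.11) did not pass. Map2k2 passed with a replicate block (0.25, adjusted p = 0.0109) and without RPT replicate 2 (0.39, adjusted p = 0.00568). F2rl1 fell 2.48-fold and F2r rose 1.42-fold. Il6 passed narrowly (-1.22, SE 0.43, adjusted p = 0.0378) and did not pass under DESeq2 (-1.23), without a filter on low counts (-1.22), or without RPT replicate 1 (-1.22), 2 (-1.26) or 3 (-1.16) or RPTi replicate 2 (-0.91) or 3 (-1.17). Without TMM factors, 2359 genes rose and 3788 fell (38.4% rising, against 49.2%), and on log2(FPKM + 1) 36.8% of called genes rose.

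**Figure D3:**
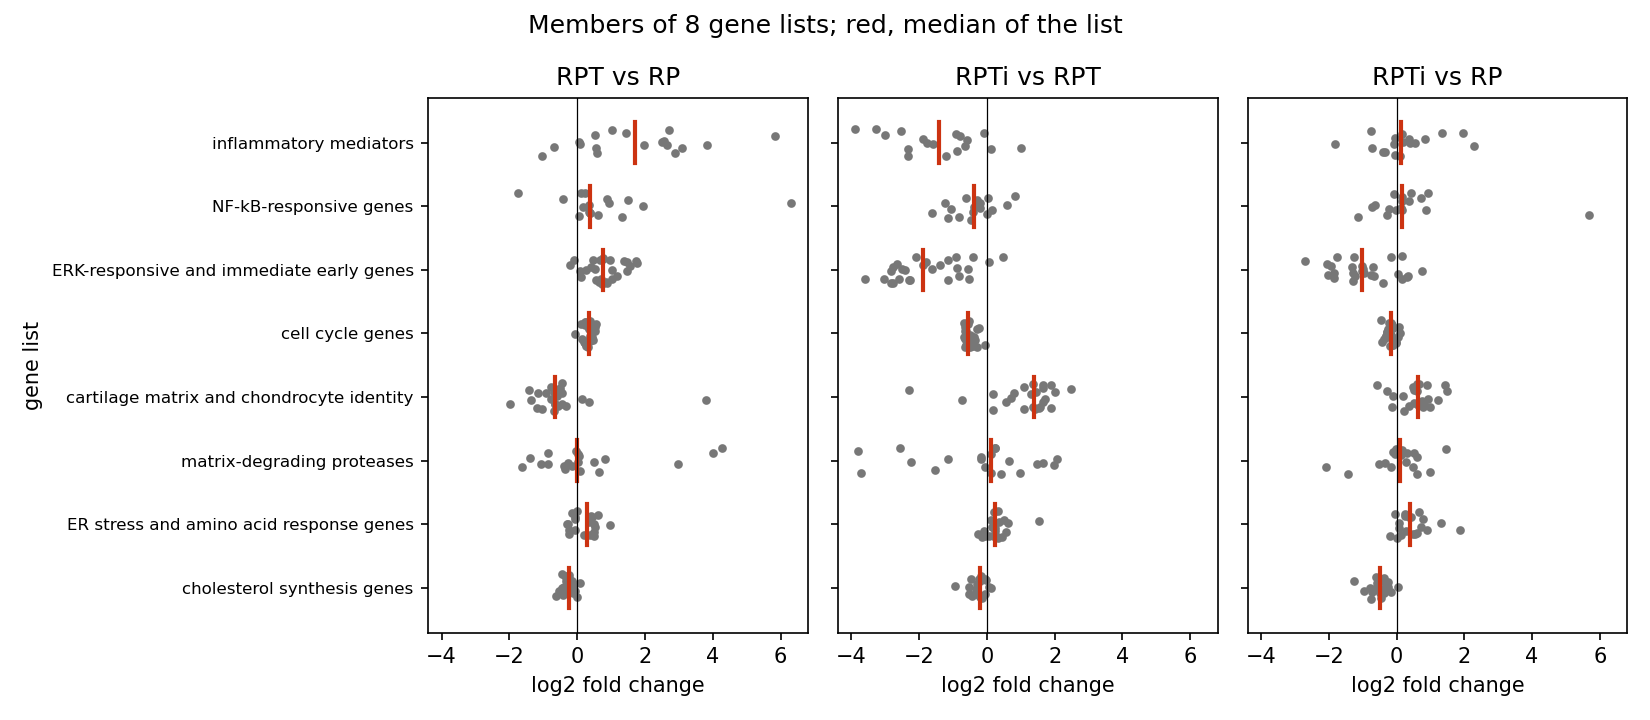
Log2 fold changes of the tested members of 8 gene lists (1 grey point per gene) in RPT against RP, RPTi against RPT and RPTi against RP, with the list median as a red bar. The median of the ERK-responsive genes is 0.76, -1.89 and -1.03 in the 3 comparisons, and that of the cartilage genes is -0.66, 1.40 and 0.62.

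Most thrombin changes were opposed with the inhibitor. Of the 1886 genes that thrombin raised, 1333 were lower in RPTi than in RPT, and of the 2113 that it lowered, 1553 were higher, in total 2886 genes or 72.2%. Without TMM factors the balance of opposed genes turned, with 1630 raised and 1361 lowered by thrombin. Independent lists would share 397 and 431 genes. Among genes that met the naming filters, the 6 opposed ones with the largest thrombin change were C3, Chi3l1, Mmp3, Pla2g2a, Lcn2 and Prg4. Opposed does not mean reversed. C3 kept most of its rise, with log2 fold changes against RP of 6.30 in RPT and 5.68 in RPTi, while Mmp3 lost most of its rise. A second change in the same direction was found for 40 raised and 66 lowered genes.

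Both contrasts use the RPT libraries, and in simulations with no effect the fold changes of the contrasts correlated at a mean of -0.51 across genes, against the observed -0.71. The covariance was -0.2888, against a simulated mean of -0.0271, a difference of -0.2617. At most 1 simulated gene was opposed, but with no effect hardly any gene was called, so that count is no reference for the observed one. With 3 RPT libraries the group could not be divided into parts of at least 2 libraries, so part of the excess may come from the shared libraries. Genes are not independent replicates.

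The following counts of opposed genes per list were not tested for a difference between lists. All 20 ERK-responsive genes raised by thrombin were opposed, and 16 of them ended below the plasma level, such as Fosl1 at 5.24 ± 1.02 CPM in RPTi against 18.7 ± 1.21 CPM in RP (SD, n = 3). Of 23 cartilage genes changed by thrombin 20 were opposed, and 16 changed past the plasma level to the other side. Of 13 inflammatory mediators 12 were opposed, and 9 did not differ from plasma in RPTi. None of the 10 cholesterol synthesis genes lowered by thrombin were opposed, and 2 of the 11 ER stress genes were. Nup210 and Ppp1r15a rose at least 2-fold with thrombin and were not opposed (log2 fold changes in RPTi against RPT of -0.34 and -0.06). These last genes were chosen after their values were seen, as the pair that met the naming filters among 40 such genes.

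**Figure D4:**
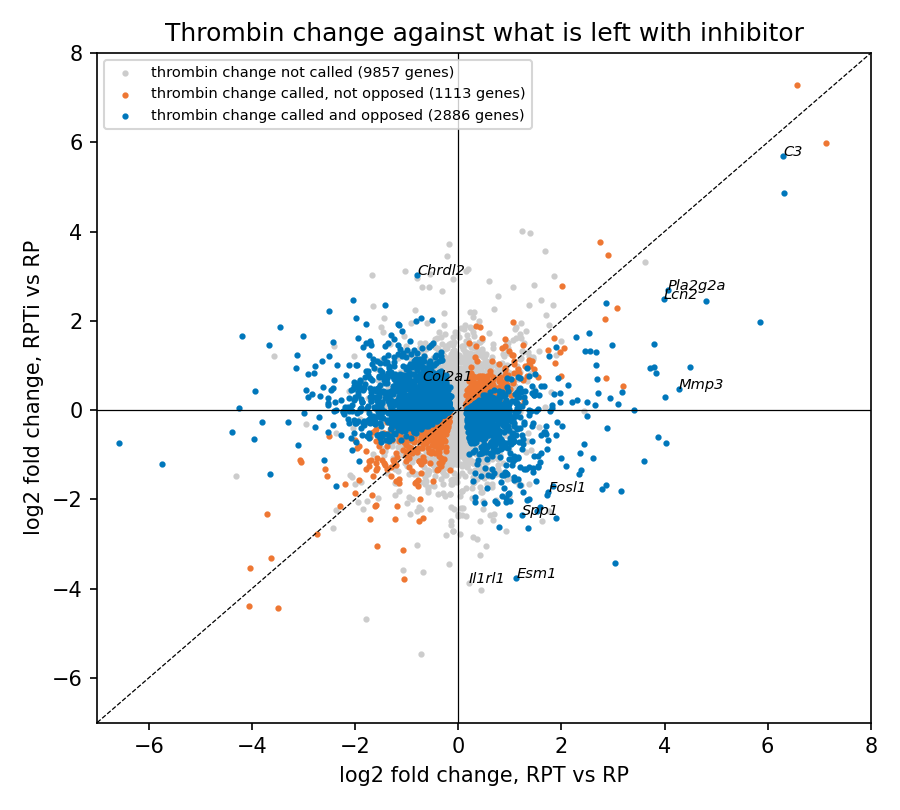
Log2 fold change of RPTi against RP (vertical) by that of RPT against RP (horizontal), with 1 point per tested gene. Blue marks the 2886 genes changed by thrombin and opposed with the inhibitor, orange the other genes changed by thrombin and grey the rest, and the dashed diagonal marks an unaltered thrombin change. C3 stays close to the diagonal at 6.30 and 5.68, and Mmp3 lies far below it at 4.27 and 0.48.

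Compared with plasma alone, cells given thrombin and inhibitor kept higher C3 and Lcn2, had higher cartilage matrix genes, and had lower ERK-responsive and cholesterol synthesis genes. The cartilage and cholesterol lists did not pass with an estimated correlation (adjusted p = 0.0664 for each with an estimated correlation). C3 was at 18.8 ± 3.20 CPM against 0.370 ± 0.0764 CPM, a 51.3-fold rise, and Lcn2 was 5.64-fold higher (SD, n = 3). Acan was 2.35-fold and Col2a1 1.58-fold higher than in plasma. Spp1 was 5.07-fold lower and Mmp13 4.23-fold lower. Of 13856 genes, 1647 rose and 1705 fell, and of those changed by at least 1 on the log2 scale 244 rose and 284 fell.

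Under the naming rule, with its limit on CPM, the largest rises were those of C3 (5.68, SE 0.19), Chrdl2 (3.02, SE 0.18) and Pla2g2a (2.69, SE 0.14), and the largest falls those of Il1rl1 (-3.86, SE 0.12), Esm1 (-3.76, SE 0.23) and the aldehyde dehydrogenase gene Aldh3a1 (-3.05, SE 0.10). Of the genes that thrombin raised, 305 were above plasma in RPTi, 362 were below it and 1219 did not differ at the threshold. Of those it lowered, 352 were below, 487 above and 1274 not different.

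Cartilage matrix genes rose in 18 and fell in 1 of 24 cases (camera adjusted p = 9.77e-13, adjusted p = 0.0664 with an estimated correlation), with Prg4 2.81-fold, Cilp2 2.71-fold and Fmod 1.89-fold higher and Sox9 not past the threshold (-0.11, adjusted p = 0.429). ERK-responsive genes fell in 19 and rose in 2 of 27 cases (adjusted p = 5.49e-10, adjusted p = 0.0194 with an estimated correlation), the transcription factor gene Etv1 6.48-fold. Cholesterol synthesis genes fell in 16 of 21 cases and none rose (adjusted p = 9.24e-12, adjusted p = 0.0664 with an estimated correlation), with Hsd17b7 2.39-fold and Hmgcs1 1.94-fold lower. Contractile genes rose in 12 of 21 cases and none fell (adjusted p = 1.34e-07, adjusted p = 0.153 with an estimated correlation), Acta2 by 4.17-fold. ER stress and amino acid response genes rose in 13 of 20 cases and none fell (adjusted p = 1.77e-08, adjusted p = 0.0268 with an estimated correlation), Atf3 by 3.67-fold and Trib3 by 2.50-fold. Cell cycle genes fell in 8 of 29 cases and none rose (adjusted p = 0.000284, adjusted p = 0.036 with an estimated correlation).

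TGF-beta-responsive genes rose in 10 and fell in 4 of 20 cases (adjusted p = 0.00233, adjusted p = 0.0839 with an estimated correlation). NRF2 and metallothionein genes fell in 5 and rose in 2 of 15 cases (adjusted p = 0.00705, adjusted p = 0.0894 with an estimated correlation), with Nqo1 2.22-fold lower. Hypoxia and glycolysis genes rose in 5 and fell in 2 of 20 cases (adjusted p = 0.0294, adjusted p = 0.149 with an estimated correlation). Fibroblast-type markers fell in 7 and rose in 2 of 16 cases (adjusted p = 0.0339, adjusted p = 0.115 with an estimated correlation), with Pdgfra 1.89-fold lower. The inflammatory mediators did not pass as a list (2 rose and 3 fell of 18, adjusted p = 0.83), and within it the interferon-induced chemokine Cxcl10 fell 3.49-fold. Nor did proteases (7 rose and 4 fell of 20, 0.252), STAT3-responsive (6 rose and 3 fell of 20, 0.409), NF-kB-responsive (6 rose and 4 fell of 17, 0.143), interferon-stimulated (1 rose and 3 fell of 18, 0.426), hypertrophic (6 rose and 3 fell of 13, 0.423), coagulation (5 rose and 5 fell of 18, 0.751), p53-responsive (5 rose and 3 fell of 13, 0.426), mitochondrially encoded (3 rose and 1 fell of 13, 0.717), macrophage (0 rose and 1 fell of 6, 0.292), endothelial (0 rose and 1 fell of 4, 0.689), blood cell (0 of 2 passed, 0.532) or muscle and fat lists (4 rose and 3 fell of 9, 0.423). Adjusted over the list alone, 20 cartilage, 4 ERK-responsive, 4 inflammatory, 7 STAT3-responsive, 14 ER stress and 6 coagulation genes rose, and 2 cartilage, 20 ERK-responsive, 19 cholesterol, 11 cell cycle, 9 NRF2, 6 coagulation, 4 p53-responsive and 3 macrophage genes fell, with the other counts as over all genes.

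Stat3 (-0.07, adjusted p = 0.33), Mapk3 (-0.11, adjusted p = 0.308), Map2k1 (-0.15, adjusted p = 0.191) and Map2k2 (0.24, adjusted p = 0.137) did not pass, and neither did Il6 (1.34, adjusted p = 0.0834). Map2k2 passed with a replicate block (adjusted p = 0.0173), without RPT replicate 2 (0.0477) and in a fit of only the groups compared (0.0332), Mapk3 with a replicate block (0.0426), and Il6 without RPTi replicate 2 (0.0487). Adamts5 rose 1.51-fold, and Mmp3 stayed 1.39-fold above plasma. Without TMM factors, 1318 genes rose and 2280 fell (36.6% rising, against 49.1%), and on log2(FPKM + 1) 37.7% of called genes rose. F2r rose by 0.25 but did not pass without TMM factors (0.20), on log2(FPKM + 1) (0.18) or without RP replicate 1 (0.28), 2 (0.24) or 3 (0.22) or RPTi replicate 2 (0.19) or 3 (0.26).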

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

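The 18 additional list tests were chosen after the results were seen: 13 passed with the preset correlation and 12 with an estimated one. They were adjusted among themselves, apart from the 69 tests of the fixed lists, so the adjusted p-values cannot be compared between these sets. All other alternatives were chosen before the data were examined.

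Of 4077 alternative values for 228 pairs of named gene and comparison, 4006 kept their side of the threshold, 34 were no longer past it, 37 came past it and 0 of the called ones reversed. Among genes not called in the report, 17 values changed sign. That count left out the fits of only the groups compared and those on log2(FPKM + 1). Mmp13, F2r and Il6 are given with their values in the report. Il6 in RPTi against RP came past the threshold without RPTi replicate 2 (1.64, against 1.34).

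A limit of at least 1 on the log2 fold change left 711 genes for RPT against RP, 1296 for RPTi against RPT and 528 for RPTi against RP, of which 30.5%, 61.8% and 46.2% rose (without the limit 47.2%, 49.2% and 49.1%), by construction a part of the genes counted without it. Under the other scalings, filters and tests the counts were 3318 to 5074, 5463 to 6698 and 3222 to 4689, the highest of each with a block for the replicate number. That block gave 7799 genes across the 3 groups, 3603 opposed genes and 35 list tests past the threshold. Whether the replicate numbers pair the libraries is not stated. Correlations between libraries of the same number, with group means removed, were -0.114 to 0.124, and 3 of 9 libraries correlated best with a library of their own number, so the numbers were not shown to pair the libraries and the block served only as an alternative.

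Leaving out 1 library at a time gave 2889 to 3957 genes for RPT against RP (lowest without RP replicate 1), 4733 to 5893 for RPTi against RPT and 2274 to 3992 for RPTi against RP (both lowest without RPTi replicate 1), 5344 to 6570 across the 3 groups, 2222 to 2795 opposed genes and 35 to 37 list tests.

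Of 69 list tests, 35 passed with the preset correlation, 10 with a correlation estimated from the data and 54 with fry, which tests each list by itself. All 35 passed with fry too. Matrix-degrading proteases in RPT against RP ranked down with camera and passed upward with fry (adjusted p = 0.00493), in a list with members at -1.62 to 4.27. The replicate block ended the call of ER stress genes in RPT against RP (adjusted p = 0.0789) and added p53-responsive genes (adjusted p = 0.0402), and the cause was not tested.

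One count corresponded to 0.0227 to 0.0314 CPM. Genes below the filter, such as Il1b and F2rl3, were therefore not tested, and changes of Il6 and F2rl2 rest on few counts.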

Other observations

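The 6 additional lists, the comparison of cartilage genes with fibroblast-type markers and the tests of ERK-responsive genes against scaling and against a general lowering were chosen after the results were seen, as were the genes named from those lists. The adjusted p-values of the additional lists cover their own 18 tests only. They are not firmer evidence than the larger adjusted p-values of the fixed lists, which cover 69 tests.

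Enzymes that build glycosaminoglycan chains followed the cartilage matrix genes. Of 25 tested, 0 rose and 13 fell with thrombin (14 falling when adjusted over the list alone), 16 rose in RPTi against RPT (1 fell when adjusted over the list alone), and 11 rose and 1 fell in RPTi against RP (3 falling when adjusted over the list alone), with adjusted p = 0.0328, 0.0328 and 0.0345 with an estimated correlation. The sulfate transporter gene Slc26a2 was at -1.11 with thrombin and 1.16 in RPTi against RPT. Xylt1, which starts the chains, was at -0.71, 1.50 and 0.80 in the 3 comparisons. Of 26 collagen folding and secretion genes, 2 rose and 15 fell with thrombin, 23 rose and 1 fell in RPTi against RPT, and 18 rose in RPTi against RP (adjusted p = 0.0454, 0.0345 and 0.0345 with an estimated correlation). Adjusted over the list alone, 16, 2 and 1 of them fell. The collagen chaperone gene Serpinh1 was at -0.39, 0.95 and 0.56, and Colgalt2, which glycosylates collagen, at -0.83, 1.96 and 1.13.

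Growth plate signalling genes fell in 13 and rose in 5 of 23 cases with thrombin, and rose in 13 and fell in 7 in RPTi against RPT (adjusted p = 0.0345 and 0.037 with an estimated correlation). The joint growth factor gene Gdf5 was at -1.66 and 2.81, the receptor gene Fgfr3 at -1.14 and 1.75, and the Wnt antagonist gene Frzb at -1.07 and 1.80. In RPTi against RP the list did not pass (11 rose and 8 fell, adjusted p = 0.0719). Adjusted over the list alone, 15 rose in RPTi against RPT and 12 in RPTi against RP. Of 13 complement genes, 4 rose and 2 fell with thrombin and the list did not pass (adjusted p = 0.15), nor did it in RPTi against RPT (4 rose and 4 fell, adjusted p = 0.901). In RPTi against RP, 5 rose and 2 fell (6 and 3 adjusted over the list alone; adjusted p = 0.0202, adjusted p = 0.0999 with an estimated correlation), with the classical pathway genes C1s and C1r at 1.42 and 0.71.

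The opposed thrombin changes were weighed against noise in the shared RPT libraries and against transcript length. Their covariance, -0.2888, lay below the lowest of 20 simulations with no effect, -0.0301, and 99.6% of it was left after a trend with transcript length was removed, which argues against each as the whole source. Inhibition of the thrombin signal may account for part of the opposition. A block of the added thrombin alone would not take genes past their plasma level. Yet 362 genes raised by thrombin ended below plasma in RPTi and 487 lowered ones above it, against 232 and 251 for independent lists. These values argue against such a block as the whole source of the changes in those genes. A further 305 raised genes stayed above plasma and 352 lowered ones below it, while 1219 and 1274 did not differ at the threshold. Effects of the inhibitor apart from thrombin stay open, since no library had the inhibitor without thrombin.

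The lower cartilage matrix genes with thrombin were weighed against 3 technical or cellular explanations. A lower share of chondrocytes among fibroblast-type cells would by itself raise the fibroblast-type markers alike, but 7 of them fell and 4 rose. Thrombin may also change these markers within cells, and the rule was set after the counts were seen, so they cannot measure the cell mix. The median of the cartilage list was -0.66, and it was -0.63 after a trend with transcript length was removed and -0.66 (-0.664) with the 20 most abundant genes, 3 of them in this list, left out of the library sizes. Those 20 genes took 17.3% to 17.5% of the counts in RP and 15.7% to 16.0% in RPT. A smaller share in RPT would by itself raise the other genes there, not lower them. These values argue against transcript length as the whole source and against a few abundant genes as a source of the lower median. A lower share of chondrocytes stays open. A response of the chondrocytes to thrombin in plasma may account for the pattern, as a hypothesis. Whether thrombin acted on the cells directly was not tested.

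ERK-responsive genes below the plasma level in RPTi were weighed against scaling and against a general lowering of thrombin-raised genes. The list's median in RPTi against RP was -1.03 with TMM, -1.02 (-1.017) with DESeq2 size factors and -1.08 with library totals alone, while the median of all genes was -0.01, 0.00 (0.001) and -0.06. These scalings differ too little to have brought the list near 0. A scaling moves all genes alike, however, and the list lay -1.02 from the median of all genes under each. The 20 members that thrombin raised had a median of -1.13 in RPTi against RP, while 24 thrombin-raised inflammatory and NF-kB-responsive genes had a median of 0.28, a difference of -1.41 (-1.407), with quartiles of -1.77 and -0.60 against -0.03 and 0.74. This did not allow for the size of the thrombin rise. Thrombin-changed inflammatory mediators went from a median of 2.55 with thrombin to 0.37 in RPTi against RP, and ERK-responsive genes from 0.92 to -1.13. NF-kB-responsive genes went from 0.50 to 0.16, a smaller drop. The distance of the list from the median of all genes argues against scaling as the whole source. A lowering shared by ERK-responsive genes and inflammatory mediators stays open. RNA amounts per cell were not measured, and ERK activity below its level in plasma may account for the pattern, as a hypothesis that protein data would have to test. Whether such a fall needs thrombin stays open, since no library had the inhibitor in plasma alone.

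A candidate explanation for lower Aldh3a1 and Nqo1 in RPTi against RP is lower activity of the aryl hydrocarbon receptor. Of its 7 other tested targets and regulators, 85.7% fell, among them Cyp1a1 (-1.47), the receptor gene Ahr (-0.89), the repressor gene Ahrr (-0.72) and Tiparp (-0.66), while the transporter gene Slc7a5 rose (0.63; list adjusted p = 0.0345 with an estimated correlation). In RPTi against RPT 5 fell and 0 rose (adjusted p = 0.0345 with an estimated correlation), and with thrombin 3 rose and 2 fell (adjusted p = 0.402; 4 rose when adjusted over the list alone). Cyp1a1 and Ahrr had already fallen with thrombin alone (-1.30 and -0.43), and Cyp1a1 did not pass in RPTi against RPT (-0.17, adjusted p = 0.221), so its fall is not tied to the inhibitor. Lower NRF2 activity stays open, since Nqo1 is in that list too and Nfe2l2 fell (-0.36).

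The rise of Acta2 and Lmod1 in RPTi against RP may belong to a wider rise of sarcomere and smooth muscle genes. Of 22 tested genes outside the earlier lists, 8 rose, 2 fell and 12 did not pass (adjusted p = 0.0345 with an estimated correlation, and 0.0345 too without Mylk, which had been seen before), with the myosin gene Myh11 at 0.70 and the smoothelin gene Smtn at 0.44. In RPTi against RPT 11 rose and 3 fell (adjusted p = 0.037 with an estimated correlation), and with thrombin 2 rose and 5 fell (adjusted p = 0.294). Adjusted over the list alone, 12 rose in both RPTi comparisons.

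Other splits of the libraries were counted for each comparison. For RPT against RP (3999 genes, highest other split 0), RPTi against RPT (5745 and 0) and RPTi against RP (3352 and 2), the real split was the 1 of 10 with as many genes, and 10 splits are too few for a share below 0.05. Over 100 splits into 3 groups, the real one included, only the real one gave as many genes (6471, highest other 2370). The same held for opposed genes (2886, highest other 1907) and for list tests past the threshold (35, highest other 28). A random split of these libraries is thus unlikely to give such counts of genes or opposed genes. The libraries of a group may be technical replicates, so chance differences between cultures are not excluded. The split with 2370 genes kept the RPTi libraries together and mixed RP with RPT, and 78 of the other 99 gave 0 genes. The median number of list tests past the threshold over the other splits was 17 of 69. Many lists thus passed at the preset correlation with wrong groupings too, so the count of 35 is weak evidence of group differences.

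Some genes varied strongly within groups. AABR07067506.1, a gene with no assigned symbol, differed up to 24-fold between libraries of a group. Mt-nd4 differed up to 10.5-fold, Ppial4d 7.6-fold, Col1a2 3.2-fold and Cenpf 3.2-fold. The 1386 genes with the longest transcripts lay 0.22 above the 1386 with the shortest in RP replicate 3 and at -0.16 from them in RPT replicate 2, in log2 deviations from the mean of all libraries, with the other 7 libraries between.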
